A study of Rattus norvegicus with 21 samples.

How the data were processed

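Forebrain astrocytes of Sprague Dawley rats were profiled on Affymetrix rat genome expression arrays. The labels describe 7 groups of 3 biological replicates each, 21 arrays in all. Cells isolated by panning on the integrin ITGB5 were lysed at once at postnatal day 1 or 7 (fresh P1 cells, fresh P7 cells). Others were grown for 7 days in serum-free medium with HBEGF at 5 ng/ml (HBEGF P1 cultures, HBEGF P7 cultures). Panned P7 cells were also grown for 7 days in 10% foetal calf serum (serum P7 cultures), and some of those were washed and kept 7 more days in HBEGF medium (withdrawn P7 cultures). MD cultures were made from P1 forebrain by the older method of McCarthy and de Vellis in 10% serum. The characteristics label of the HBEGF P7 cultures says p1, while the title and the source name say P7, and the title was followed. Per the labels' protocols, RNA was taken with a QIAGEN RNeasy mini kit and labelled with the 3' IVT Express kit. The series also mentions RT-PCR for contamination, whose values were not used here.

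The values were the authors' deposited intensities, 1 per probe set and array, made by RMA per the submitters' processing notes. The RMA software, its version and the chip definition are not given in the sources used here. The deposited intensities ran from 10 to 37801 with array medians between 128 and 146, so they were on the linear scale, and log2 of them was used. No intensity limit was set. The table held 31042 probe sets and 0 control probe sets. Of these, 20826 carried 1 gene symbol, 436 several and 9780 none. Genes were counted through 1 probe set each, the probe set with the highest mean over all arrays among those with 1 symbol, which gave 14217 genes, 4525 of them with more than 1 probe set. By gene number, 20758 probe sets were matched to the reference table. Near-identical paralogs, such as Hspa1a with Hspa1b, the Gsta1 family and Lyz2, cannot be told apart with certainty by their probes.

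Groups were compared with limma (lmFit, contrasts.fit and eBayes with default settings) in 1 model of 7 group means with 14 residual and 2.89 prior degrees of freedom. A change was called at an adjusted p (Benjamini-Hochberg within a comparison, over all probe sets) under 0.05 and an absolute log2 change of at least 1. Every log2 change below is from this fit unless said otherwise, adjusted p values are of limma, and SE is the moderated standard error. Values per group are log2 intensity, mean ± SD. With 3 arrays per group, which limits precision, an exact two-sided permutation test cannot give a p under 0.1.

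Gene lists written from textbook knowledge were fixed before the tests: 22 lists with 458 entries, 418 of them measured. No probe set used here carried 37 listed symbols, among them Sox9 and Gapdh, as its single symbol. The lists cover astrocyte, neuron, oligodendrocyte progenitor, oligodendrocyte, microglia and macrophage, endothelial, mural, and fibroblast and meningeal markers; cell cycle genes; immediate-early genes; cytoskeletal targets of serum response factor (SRF); reactive astrocyte genes; extracellular matrix; cholesterol synthesis; glutamate, GABA and ion transport; secreted factors that act on synapses; phagocytosis; progenitor and Notch genes; glycolysis; interferon and antigen presentation; feedback genes of EGFR and MAPK signalling; and TGF-beta and BMP response genes. A list is described by the number of members that rose, fell or were not called, both with p adjusted over all probe sets and with p adjusted over the list alone. It was tested with camera of limma at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 22 lists of a comparison, and again with the correlation estimated from the residuals. Of 105 camera calls at the preset correlation, 12 held with the estimated correlation, and the text gives both values.

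The samples, the tests, the call rule and the alternatives were chosen before the data were examined. The genes named were picked by rule: the 8 largest rises and 8 largest falls of each comparison among called genes whose arrays did not overlap between groups, up to 4 called members with the largest change in a list that is described, and in each comparison Gfap, Aqp4, Aldh1l1, Slc1a2, Slc1a3, Gja1, S100b, Itgb5, Hbegf and Egfr. Of 710 calls of genes named this way over all comparisons, 165 were lost when some 1 array was left out. Not all of these genes appear in the report, and where it gives a gene's value without 1 array, leaving out others can end the call too. Of the 16 largest changes, all stayed called with any 1 array left out in 6 comparisons, 15 in MD against HBEGF P1 cultures and in withdrawn against serum P7 cultures, 13 in fresh P7 against fresh P1 cells and 8 in HBEGF P7 against HBEGF P1 cultures.

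The code was tried on simulated data first. Simulated changes of 1.5 log2 were recovered in 74.6% to 88.1% of cases, of 2 log2 in 89.6% to 98.5% and of 3 log2 in 90.9% to 100%, with at most 7 false calls. The alternatives were each array left out in turn, a replicate block, array weights, repeated quantile normalization, arrays centred on their medians, an intensity filter, a stricter p, no fold limit, a test against a fold of 1.5, the mean of all probe sets of a gene, and fits on the compared groups only. Repeated normalization or centring moved the share of changes that are rises by at most 9.5 percentage points. An alternative that leaves out replicates 2 and 3 of the HBEGF P7 cultures was added after the data were seen, since their fibroblast and microglia markers differed from each other.

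Replicate numbers were tested for pairing: the residuals of same-numbered arrays were correlated over 0.1 in every pair in 5 of 10 comparisons (HBEGF P1 cultures with fresh P1 cells, HBEGF P7 with HBEGF P1 cultures, MD cultures with fresh P1 cells, MD with HBEGF P1 cultures, and withdrawn with serum P7 cultures). The labels do not say that numbers mark shared preparations, so the main tests are unpaired. No paired fit of the compared groups was run. Below, a value with a replicate block over all groups is given only where it moves the call.

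No detection calls were used, so changes from or to low intensities are changes in intensity only. Left out were the cell files, probe sets without a symbol when genes are counted, and any splice or protein level.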

Results

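The arrays compare fresh astrocytes of P1 and P7 rats with cultured ones. Some astrocyte genes stayed high in every group: Gfap, the glial filament protein, lay between 12.50 ± 0.41 (SD, n = 3) in fresh P1 cells and 14.69 ± 0.07 (SD, n = 3) in serum P7 cultures. Gja1, the main astrocyte gap junction protein, lay between 13.85 and 14.70 in the 7 groups, and Slc1a3, the glutamate transporter GLAST, between 13.26 and 14.72. Others did not: Aldh1l1 was at 12.50 in fresh P1 cells and 8.65 in MD cultures, and Slc1a2 at 10.37 in fresh P7 cells and 6.14 in withdrawn cultures. Egfr, the receptor that HBEGF activates, was at 12.60 and 12.17 in the HBEGF P1 and P7 cultures, but at 9.21 in MD, 9.66 in serum and 10.02 in withdrawn cultures. Immediate-early genes had a list mean of 12.20 and 12.38 in the fresh P1 and P7 cells and between 8.31 and 9.06 in the cultures.

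The first 3 principal components held 41.9%, 19.9% and 12.4% of the variance. Spearman correlations between arrays of 1 group ran from 0.963 to 0.994, the lowest inside the HBEGF P7 cultures. Between groups the lowest median correlation was 0.90, between fresh P1 cells and withdrawn P7 cultures, and fresh P1 and fresh P7 cells correlated at a median of 0.978. The median SE of a log2 change over all genes was 0.17.

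**Figure D1:**
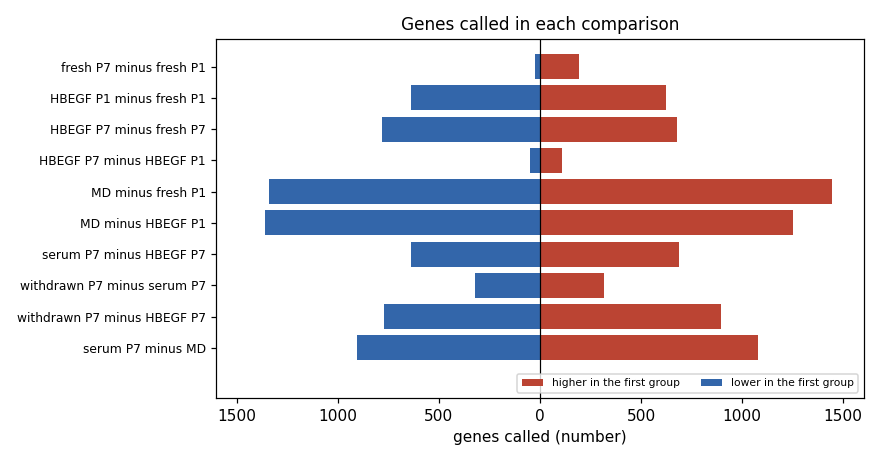
Number of genes called higher (to the right) and lower (to the left) in the first-named group of each of the 10 comparisons. MD cultures against fresh P1 cells had the most calls, 1442 higher and 1340 lower, and HBEGF P7 against HBEGF P1 cultures the fewest, 107 and 51.

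Between P1 and P7 some genes of transmitter handling rose in the fresh cells. Slc1a2, the glutamate transporter GLT-1, and Grin2c, an NMDA receptor subunit found in astrocytes, both rose. So did Gabbr2, a subunit of the GABA-B receptor, and Mertk, a receptor with which astrocytes engulf synapses. The heat shock gene Hspa1a had the largest rise. Igfbpl1 and Neurod1, genes of young neurons, and Cldn5, the tight junction protein of endothelium, fell.

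Hspa1a went from 9.30 ± 0.13 (SD, n = 3) to 13.30 ± 0.35 (SD, n = 3), a log2 change of 4 (adjusted p = 6.01e-07). Grin2c rose by 3.18 (adjusted p = 1.82e-07), Plppr5 by 3.08 (adjusted p = 0.00701), Plekhd1 by 2.81 (adjusted p = 0.000471), Gpr37 by 2.66 (adjusted p = 0.00201), Ccdc141 by 2.62 (adjusted p = 2.99e-09) and Gabbr2 by 2.58 (adjusted p = 0.000884). The plasma protein gene Alb rose by 2.65 (adjusted p = 0.0127), a call lost without fresh P1 replicate 2 (adjusted p = 0.0752). Among the falls were Dct, a melanin enzyme (-2.37, adjusted p = 1.41e-08), Cldn5 (-2.15, adjusted p = 0.000243), the transcription factor Tfap2c (-2.05, adjusted p = 0.00161), the amino acid transporter Slc38a5 (-1.75, adjusted p = 0.000698), Cnpy1 (-1.70, adjusted p = 0.00027) and the neuronal hydrolase Uchl1 (-1.67, adjusted p = 0.00608). Igfbpl1 (-3.86, adjusted p = 0.0356) and Neurod1 (-2.01, adjusted p = 0.0384) fell too, but each call was lost without any 1 of the 6 arrays, with adjusted p up to 0.136 and 0.127 without fresh P1 replicate 3.

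Of the core astrocyte genes, Slc1a2 rose by 2.12 (adjusted p = 1.05e-05) and Gfap by 1.34 (adjusted p = 0.0159; 0.0724 without fresh P7 replicate 1, not called). Gja1 was 0.40 higher (adjusted p = 0.0328, under the fold limit). Aqp4 (0.64), S100b (0.51), Slc1a3 (0.19), Aldh1l1 (0.06), Itgb5 (0.06), Egfr (0.35) and Hbegf (-0.10) were not called (adjusted p from 0.17 to 0.952).

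The astrocyte list had 5 of 28 members up and 0 down (5 adjusted over the list alone), with a median change of 0.55 and camera adjusted p = 8.32e-09, but adjusted p = 0.263 with an estimated correlation. Slc1a2 and the receptor Gpr37l1 (2.03, adjusted p = 0.00312) were called, and so were Ntsr2 (2.47, adjusted p = 0.0343) and Cldn10 (2.40, adjusted p = 0.0107), lost without any 1 of the 6 arrays and without fresh P1 replicate 2 in turn. The count was 3 without fresh P1 replicate 1 or 2 or fresh P7 replicate 1. In the glutamate, GABA and ion transport list 4 of 17 rose (4 adjusted over the list alone; camera adjusted p = 3.46e-08, adjusted p = 0.062 with an estimated correlation). Beside Slc1a2 they included the serine and glycine carrier Slc7a10 (1.61, adjusted p = 0.000918), the GABA transporter Slc6a11 (1.27, adjusted p = 0.00795) and the glutamine transporter Slc38a3 (1.10, adjusted p = 0.0166; 0.0661 without fresh P1 replicate 2). For phagocytosis, Mertk (1.71, adjusted p = 0.00485) and the cholesterol exporter Abca1 (1.12, adjusted p = 0.0173; 0.0781 without fresh P1 replicate 2) rose out of 16 (2 adjusted over the list alone; camera adjusted p = 0.00524, adjusted p = 0.286 with an estimated correlation). Only 1 phagocytosis gene rose without fresh P1 replicate 2 or 3 or fresh P7 replicate 1 or 2. Cell cycle genes had a median change of -0.45 (camera adjusted p = 7.8e-05, adjusted p = 0.573 with an estimated correlation), with 0 of 33 called by limma and 7 lower at unadjusted p under 0.05 (0 adjusted over the list alone). The largest was E2f1 (-0.85, adjusted p = 0.0506).

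Few markers of other cells were called in the same comparison. Microglia and macrophage genes had a median change of 1.20 (camera adjusted p = 0.00233, adjusted p = 0.532 with an estimated correlation), with 2 of 18 called (5 adjusted over the list alone): Csf1r (1.97, adjusted p = 0.0417) and P2ry12 (1.37, adjusted p = 0.0166). Neither stayed called without fresh P7 replicate 1 (adjusted p = 0.182 and 0.0865), nor without fresh P1 replicate 1 or 2. Fibroblast and meningeal genes had a median of 0.88 (camera adjusted p = 0.00257, adjusted p = 0.532 with an estimated correlation), with 0 of 17 called by limma, 7 higher at unadjusted p under 0.05, 6 called when adjusted over the list alone, and 3 called without fresh P1 replicate 2. Their largest value was Lum (1.58, adjusted p = 0.0906). Neuron genes had a median of -0.29 (camera adjusted p = 0.00304, adjusted p = 0.354 with an estimated correlation), and the only call, Gap43 (-1.33, adjusted p = 0.0473; 1 of 23, 1 adjusted over the list alone), is lost without any 1 of the 6 arrays (adjusted p up to 0.143 without fresh P1 replicate 2) and with a replicate block (adjusted p = 0.052). In all 195 genes were higher and 26 lower at P7, 221 calls, against 136 without fresh P1 replicate 2.

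Growth of P1 cells for 7 days in HBEGF medium was marked by the loss of immediate-early transcripts and of several transporters of freshly isolated astrocytes. Fosb, Nr4a1, Klf4 and Atf3, transcription factors of the immediate response to stimuli, had some of the largest falls. Grm3, the metabotropic glutamate receptor of astrocytes, and Slco1c1, a carrier of thyroid hormone, fell as well. Some mitotic and sterol synthesis genes were also lower, while Gfap, the detoxifying enzyme Gsta1 and the sodium channel Scn7a rose.

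Fosb went from 13.35 ± 0.05 (SD, n = 3) to 4.72 ± 0.12 (SD, n = 3), a log2 change of -8.63 (adjusted p = 2.78e-16). Nr4a1 fell by 6.90 (adjusted p = 2.93e-12), Klf4 by 6.53 (adjusted p = 2.97e-07), Grm3 by 6.05 (adjusted p = 1.6e-09), Slco1c1 by 5.86 (adjusted p = 3.6e-10), Csrnp1 by 5.51 (adjusted p = 4.63e-10), Atf3 by 5.45 (adjusted p = 2.14e-07) and the secreted protease Adamts1 by 5.38 (adjusted p = 1.02e-09). Rises were led by Gsta1 (6.38, adjusted p = 1.35e-09), Scn7a (6.14, adjusted p = 7.51e-07), the GABA-making enzyme Gad1 (4.50, adjusted p = 0.00217), the organic cation transporter Slc22a3 (4.40, adjusted p = 1.36e-05), the neurotensin receptor Ntsr2 (4.02, adjusted p = 0.00015), the calcification inhibitor Mgp (4, adjusted p = 1.7e-05), Gpnmb (3.97, adjusted p = 1.55e-05) and the death receptor Fas (3.74, adjusted p = 5.05e-05).

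Gfap rose by 1.90 (adjusted p = 0.000134) and S100b by 1.07 (adjusted p = 0.000856; 0.86 without fresh P1 replicate 1, under the fold limit). Aldh1l1, the folate enzyme that marks astrocytes, fell by 1.5 (adjusted p = 0.000312), Slc1a2 by 1.43 (adjusted p = 6.17e-05) and Itgb5, the panning antigen, by 1.33 (adjusted p = 0.00686). Egfr (0.84), Gja1 (0.32), Aqp4 (0.32), Slc1a3 (-0.41) and Hbegf (-0.49) were not called (adjusted p from 0.0298 to 0.635, those under 0.05 below the fold limit).

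Of 19 immediate-early genes 18 fell (18 adjusted over the list alone), with a median of -3.31, camera adjusted p = 8.02e-31 and adjusted p = 4.38e-05 with an estimated correlation. Cholesterol synthesis had 4 of 20 lower (4 adjusted over the list alone; camera adjusted p = 1.7e-09, adjusted p = 0.0331 with an estimated correlation). The sterol sensor Insig1 (-1.76, adjusted p = 3.63e-05) was called. In the cell cycle list 16 of 33 fell (19 adjusted over the list alone; camera adjusted p = 6.39e-10, adjusted p = 0.3 with an estimated correlation). That count was 9 without HBEGF P1 replicate 1 and 10 without replicate 2. Glutamate, GABA and ion transport had 6 of 17 lower (6 adjusted over the list alone; camera adjusted p = 7.13e-06, adjusted p = 0.077 with an estimated correlation), with Slc7a10 (-2.22, adjusted p = 3.92e-06) and Slc6a11 (-1.71, adjusted p = 8.69e-05). Feedback genes of EGFR and MAPK signalling, which report growth factor input, had 4 of 20 lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.000977, adjusted p = 0.236 with an estimated correlation). The ligand Areg (-5.27, adjusted p = 1.1e-06) and Dusp5 (-4.23, adjusted p = 6.89e-07) belonged to these. Rises in that list numbered 2 without fresh P1 replicate 1 or HBEGF P1 replicate 3. Endothelial genes had a median of -0.46 and 2 of 14 lower (2 adjusted over the list alone; camera adjusted p = 0.000233, adjusted p = 0.236 with an estimated correlation). Cldn5 (-4.26, adjusted p = 7.08e-09) and Kdr (-1.94, adjusted p = 0.000654) were called.

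Genes of the oligodendrocyte progenitor list rose in 3 of 7 cases (3 adjusted over the list alone), Pdgfra (3.68, adjusted p = 0.000826), Lhfpl3 (2.69, adjusted p = 0.00103) and Sox10 (1.83, adjusted p = 1.29e-05), with camera adjusted p = 0.0985. Astrocyte genes had 4 of 28 higher, 2 without fresh P1 replicate 1, and 8 lower (4 and 9 adjusted over the list alone; camera adjusted p = 0.0215, adjusted p = 0.484 with an estimated correlation). Oligodendrocyte genes had 3 of 14 higher, 1 without HBEGF P1 replicate 1, and 1 lower, 0 without HBEGF P1 replicate 2 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0587). Neuron genes had 4 of 23 higher, 2 without any 1 array but HBEGF P1 replicate 2, and 1 lower, 2 without fresh P1 replicate 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.866). In all 622 genes were higher and 639 lower.

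The P7 cells lost much the same genes in HBEGF medium, among them transmitter transporters that had come up between P1 and P7. Fosb, Nr4a1, Nr4a2 and Dusp1, all immediate-early genes, fell steeply. Grm3, Slc1a2, Slc7a10 and Slc6a11, which handle glutamate, serine and GABA, were all lower. Hes5 and Hes1, effectors of Notch signalling, fell. Calcium-binding S100a6 and the membrane organiser Anxa2 were among the largest rises.

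Fosb fell by 9.03 (adjusted p = 1.31e-16), Nr4a1 by 7.36 (adjusted p = 6.66e-13), Slco1c1 by 6.82 (adjusted p = 3.38e-11), Grm3 by 6.79 (adjusted p = 2.81e-10), the phospholipase Pla2g3 by 6.47 (adjusted p = 7.79e-08), Hspa1a by 6.38 (adjusted p = 1.07e-10), Nr4a2 by 5.97 (adjusted p = 2.01e-12) and Dusp1 by 5.74 (adjusted p = 5.04e-09). Scn7a rose by 5.94 (adjusted p = 8.8e-07) and Gsta1 by 5.14 (adjusted p = 1.41e-08). S100a6 went from 7.59 ± 0.53 (SD, n = 3) to 12.25 ± 0.49 (SD, n = 3), a change of 4.66 (adjusted p = 1.9e-09). Further rises were the amino acid transporter Slc6a15 (3.94, adjusted p = 5.1e-05), Fas (3.78, adjusted p = 3.6e-05), the stress factor Nupr1 (3.74, adjusted p = 0.000376), Rassf4 (3.70, adjusted p = 9.32e-06) and Anxa2 (3.69, adjusted p = 6.2e-06).

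Slc1a2 fell by 3.30 (adjusted p = 3.31e-09) and Aldh1l1 by 1.55 (adjusted p = 0.000194). S100b was 0.86 higher (adjusted p = 0.00422, under the fold limit). Gfap (0.46, adjusted p = 0.289), Aqp4 (-0.56, adjusted p = 0.114), Slc1a3 (-0.52, adjusted p = 0.077), Gja1 (-0.04, adjusted p = 0.824), Itgb5 (-0.81, adjusted p = 0.0846) and Hbegf (-0.53, adjusted p = 0.561) were not called, nor was Egfr (0.06, adjusted p = 0.915), for which another probe set moved in the opposite direction past adjusted p.

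The immediate-early list again had 18 of 19 lower (18 adjusted over the list alone), median -3.74, camera adjusted p = 2.66e-27 and adjusted p = 8.84e-05 with an estimated correlation. In glutamate, GABA and ion transport 10 of 17 fell (10 adjusted over the list alone; camera adjusted p = 2.73e-11, adjusted p = 0.00848 with an estimated correlation). Slc7a10 (-3.84, adjusted p = 4.11e-09) and Slc6a11 (-3.13, adjusted p = 8.9e-08) were among them. Sterol synthesis had 11 of 20 lower (11 adjusted over the list alone; camera adjusted p = 3.64e-11, adjusted p = 0.0117 with an estimated correlation). Astrocyte genes fell in 10 of 28 cases with 0 up, or 1 without HBEGF P7 replicate 2 (11 down adjusted over the list alone; camera adjusted p = 3.87e-08, adjusted p = 0.19 with an estimated correlation). Hes5 (-5.49, adjusted p = 9.52e-07) was called. Progenitor and Notch genes had 7 of 22 lower (7 adjusted over the list alone; camera adjusted p = 0.00164, adjusted p = 0.209 with an estimated correlation), Hes1 (-3.00, adjusted p = 3.29e-06), Prom1 (-2.12, adjusted p = 0.000676) and the ligand Jag1 (-1.61, adjusted p = 0.000454) after Hes5. In the same list 2 rose without HBEGF P7 replicate 3. In the fibroblast and meningeal list 4 of 17 rose and 1 fell (4 and 1 adjusted over the list alone; median 0.88, camera adjusted p = 0.159), with Mgp (3.17, adjusted p = 0.000132) and Crabp2 (2.59, adjusted p = 0.00575). The rises numbered 8 without HBEGF P7 replicate 2 and 2 without replicate 3, and the falls 0 without HBEGF P7 replicate 2 or fresh P7 replicate 1 and 2 without HBEGF P7 replicate 3. Microglia genes had 3 of 18 lower (3 adjusted over the list alone; camera adjusted p = 0.0686), with 8 lower without HBEGF P7 replicate 3 and 1 without HBEGF P7 replicate 2 or fresh P7 replicate 1. In all 680 genes were higher and 783 lower.

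The culture changes of the P1 and P7 cells shared 698 genes of the same sign, 280 higher and 418 lower, where independent lists would share 29.8 and 35.2, and 2 had opposite signs. The log2 changes of all 14217 genes correlated at r = 0.77 (covariance 0.398), and these comparisons share no arrays.

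Whether culture acted differently on the P7 cells was tested as a difference of differences. S100a6 was 1.36 higher in cultured than in fresh P1 cells and 4.66 higher in P7 cells. This difference was 3.30 ± 0.37 (SE) (adjusted p = 0.00018). Penk, which encodes enkephalin (3.54, adjusted p = 0.0206), Esm1 (3.23, adjusted p = 0.0257), Cldn5 (2.52, adjusted p = 0.00301; at 4.72 and 5.10 in the cultures, far under the median of all values, 7.11, so that the fresh levels set it) and the actin-binding tropomyosin Tpm2 (2.43, adjusted p = 0.0337) had the largest positive differences. The largest negative ones were the protocadherin Pcdh20 (-4.05, adjusted p = 0.000112), Gabbr2 (-3.95, adjusted p = 0.00102; -1.5 in P1 and -5.45 in P7 cells), Hspa1a (-3.70, adjusted p = 0.000174; at 6.62 and 6.92 in the cultures, so that the fresh levels set it too), the myelin inhibitor Omg (-3.02, adjusted p = 2.83e-05) and angiotensinogen, Agt (-2.99, adjusted p = 0.000112).

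In this test the glutamate, GABA and ion transport list had a median difference of -0.74, with 2 of 17 called (4 adjusted over the list alone; camera adjusted p = 2.24e-07, adjusted p = 0.0909 with an estimated correlation). Cell cycle genes differed by a median of 1.01, with 1 of 33 called (8 adjusted over the list alone; camera adjusted p = 9.17e-14, adjusted p = 0.347 with an estimated correlation), and astrocyte genes by -0.49, with 1 of 28 called (6 adjusted over the list alone; camera adjusted p = 2.66e-07, adjusted p = 0.279 with an estimated correlation). For cell cycle genes HBEGF P7 replicate 1 showed no such difference. Its list mean was 9.33 against 10.33 in fresh P7 cells, and P1 cells went from 10.77 to 9.72. Replicates 2 and 3 stood at 11.14 and 10.6. Of all genes 23 differed upward and 93 downward, 116 in all. The total was 50 without fresh P1 replicate 2, 75 without fresh P1 replicate 3, 64 without fresh P7 replicate 3, 61 without HBEGF P1 replicate 1 and 343 without HBEGF P7 replicate 1. The upward count ran from 4 without fresh P1 replicate 2 to 151 without HBEGF P7 replicate 1, and was 60 without HBEGF P7 replicate 2.

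Side by side, few genes separated HBEGF cultures from P7 pups and those from P1 pups, and 8 of the 16 largest changes lost their call without some 1 array. The collagen crosslinker Loxl2, the tropomyosin Tpm2 and Esm1, a secreted proteoglycan, were higher. Tnr, the tenascin of perineuronal nets, and Sox10, the transcription factor of oligodendrocyte lineage cells, were lower. None of the core astrocyte genes was called.

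Esm1 rose by 3.99 (adjusted p = 0.000409), S100a6 by 3.66 (adjusted p = 3.1e-06) and Tpm2 by 2.86 (adjusted p = 0.000805), while Tnr (-2.77, adjusted p = 0.00377), Ptprr (-2.35, adjusted p = 0.00536), Prmt8 (-2.34, adjusted p = 0.000414), Brinp1 (-2.02, adjusted p = 0.00274) and the acid-sensing channel Asic1 (-1.94, adjusted p = 0.000409) fell. The retinoic acid hydroxylase Cyp26b1 (3.38, adjusted p = 0.0162; 0.0708 without HBEGF P1 replicate 2), Tnmd (3.25, adjusted p = 0.013; 0.0584 without HBEGF P1 replicate 3), the macrophage receptor Adgre1 (2.88, adjusted p = 0.0446; 0.194 without HBEGF P1 replicate 2) and Sema3d (2.74, adjusted p = 0.0265; 0.111 without HBEGF P1 replicate 2) rose, but leaving out 1 array ended these calls for 2, 1, 5 and 3 of the 6 arrays in turn. Mfap5 (2.69, adjusted p = 0.0426) was lost for 4 arrays, with adjusted p = 0.159 without HBEGF P1 replicate 2, and with a replicate block (adjusted p = 0.0515). Likewise Myt1 (-2.51, adjusted p = 0.0396; 0.201 without HBEGF P1 replicate 2), the filament gene Ina (-1.94, adjusted p = 0.0438; 0.182 without HBEGF P1 replicate 1) and Dock10 (-1.89, adjusted p = 0.0166; 0.111 without HBEGF P1 replicate 2) fell, in calls lost for 5, 4 and 3 arrays. Gfap (-0.11), Aqp4 (-0.23), Aldh1l1 (0.01), Slc1a2 (0.25), Slc1a3 (0.08), Gja1 (0.04), S100b (0.30), Itgb5 (0.58), Hbegf (-0.15) and Egfr (-0.43) were not called (adjusted p from 0.561 to 0.997).

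Extracellular matrix genes rose in 7 of 24 cases (10 adjusted over the list alone; 4 without HBEGF P1 replicate 2; camera adjusted p = 6.15e-12, adjusted p = 0.0569 with an estimated correlation): Loxl2 (2.52, adjusted p = 0.00619), Loxl1 (1.68, adjusted p = 0.00314), and with calls lost without HBEGF P1 replicate 2 the collagen Col8a1 (1.98, adjusted p = 0.0327; 0.161) and the gelatinase Mmp2 (1.75, adjusted p = 0.0168; 0.082). Fibroblast and meningeal genes had a median of 1.07 (camera adjusted p = 1.01e-08, adjusted p = 0.195 with an estimated correlation) and 3 of 17 called (10 adjusted over the list alone). This count ran from 0 without HBEGF P1 replicate 1 or 2 or HBEGF P7 replicate 3 to 9 without HBEGF P7 replicate 2. Its list mean in the HBEGF P7 arrays was 10.57, 8.87 and 11.04 for replicates 1, 2 and 3, against 9.10 over the HBEGF P1 arrays. Col1a2 (1.71, adjusted p = 0.0361) was lost without HBEGF P1 replicate 2 (adjusted p = 0.157) and with a replicate block (adjusted p = 0.0502). Cell cycle genes had a median of 0.68 (camera adjusted p = 1.44e-09, adjusted p = 0.382 with an estimated correlation), with 0 of 33 called by limma, 14 higher at unadjusted p under 0.05 (0 adjusted over the list alone) and 20 called without HBEGF P7 replicate 1. The largest was Mki67 (1.06, adjusted p = 0.206). Neuron genes were lower by camera, with a median of -0.36 (adjusted p = 4.8e-05, adjusted p = 0.191 with an estimated correlation). Here 0 of 23 were called by limma, 9 were lower at unadjusted p under 0.05, 5 were called when adjusted over the list alone and 6 without HBEGF P7 replicate 3. The SRF list had 1 of 19 higher, Tpm2 (1 adjusted over the list alone), median 0.13, camera adjusted p = 0.0371, which is 0.0501 with a replicate block and adjusted p = 0.382 with an estimated correlation. Interferon and antigen presentation genes had a median of 1.03 (camera adjusted p = 2.08e-08, adjusted p = 0.195 with an estimated correlation) and 2 of 19 called (6 adjusted over the list alone), 0 without HBEGF P1 replicate 2 or HBEGF P7 replicate 3 and 8 without HBEGF P7 replicate 2. Sox10 was the only 1 of 7 oligodendrocyte progenitor genes that fell (-1.63, adjusted p = 0.00128; 3 adjusted over the list alone, 2 without HBEGF P7 replicate 3; camera adjusted p = 0.0133, adjusted p = 0.128 with an estimated correlation). In all 107 genes were higher and 51 lower, 158 together, but 75 without HBEGF P1 replicate 2 (30 higher, 45 lower), 98 without HBEGF P1 replicate 1 and 291 without HBEGF P7 replicate 2 (244 and 47). A replicate block over all groups gave 174. An unpaired limma fit of these 2 groups alone called 0 genes, with 357 past the fold limit at unadjusted p under 0.05 and a lowest adjusted p of 0.118.

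More genes separated MD cultures than HBEGF P1 cultures from fresh P1 cells. Contractile transcripts rose in MD cultures, such as Cnn1, the calponin of smooth muscle, and Tagln, and so did the lysyl oxidase Lox, which crosslinks collagen. Genes of glutamate handling and of sterol synthesis fell, including Grm3 and Insig1. Aldh1l1, Aqp4, Slc1a2 and Slc1a3, all astrocyte markers, fell. The ligand Hbegf rose while its receptor Egfr fell.

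S100a6 went from 7.23 ± 0.28 (SD, n = 3) in fresh cells to 13.98 ± 0.01 (SD, n = 3), a change of 6.74 (adjusted p = 8.9e-12). The guanine deaminase Gda (6.05, adjusted p = 3.92e-08), the activin antagonist Fstl3 (5.85, adjusted p = 4.79e-10), S100a4 (5.84, adjusted p = 4.16e-07), Mall (5.68, adjusted p = 6.3e-12), Lox (5.66, adjusted p = 4.14e-07), Ntng1 (5.56, adjusted p = 3.3e-08) and S100a11 (5.51, adjusted p = 8.71e-08) rose. Fosb (-8.17, adjusted p = 6.97e-16), Nr4a1 (-7.58, adjusted p = 4.24e-13), Slco1c1 (-7.40, adjusted p = 8.44e-12), Grm3 (-7.32, adjusted p = 6.39e-11), Dipk1c (-6.41, adjusted p = 4.97e-11), the retinal carrier Rlbp1 (-6.27, adjusted p = 6.87e-10), the Wnt antagonist Sfrp2 (-6.04, adjusted p = 2.61e-07) and Rnf122 (-5.99, adjusted p = 6.3e-12) fell.

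Aldh1l1 fell by 3.85 (adjusted p = 4.04e-09), Egfr by 2.54 (adjusted p = 8.82e-07), Itgb5 by 1.58 (adjusted p = 0.000897), Slc1a2 by 1.51 (adjusted p = 1.13e-05), Slc1a3 by 1.27 (adjusted p = 8.67e-05) and Aqp4 by 1.10 (adjusted p = 0.0017; -0.96 without MD replicate 3, under the fold limit). Hbegf rose by 3.42 (adjusted p = 9.92e-05). Gfap (0.93, adjusted p = 0.0158), Gja1 (-0.30, adjusted p = 0.0246) and S100b (0.18, adjusted p = 0.516) were not called.

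Of the SRF targets, which serum and tension switch on, 13 of 19 rose and 2 fell (13 and 2 adjusted over the list alone; camera adjusted p = 6.64e-05, adjusted p = 0.124 with an estimated correlation). Cnn1 (5.51, adjusted p = 4.45e-06), Tagln (4.70, adjusted p = 8.24e-08) and Tpm2 (4.51, adjusted p = 4.61e-08) were among them. In cholesterol synthesis 16 of 20 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 6.48e-13, adjusted p = 0.00599 with an estimated correlation). Insig1 (-3.68, adjusted p = 3.18e-09) and Idi1 (-2.90, adjusted p = 4.68e-09) belonged to these. Glutamate, GABA and ion transport had 15 of 17 lower (15 adjusted over the list alone; camera adjusted p = 5.73e-12, adjusted p = 0.00599 with an estimated correlation). Immediate-early genes fell in 16 of 19 cases and rose in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 2.37e-13, adjusted p = 0.0038 with an estimated correlation), including Fos (-5.39, adjusted p = 2.59e-10). Of the astrocyte list 15 of 28 fell (15 adjusted over the list alone; camera adjusted p = 3.92e-09, adjusted p = 0.114 with an estimated correlation), and 1 rose without fresh P1 replicate 2 or 3 or MD replicate 1. Reactive astrocyte genes, which mark the response to injury, rose in 15 of 26 cases and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 0.0176, adjusted p = 0.619 with an estimated correlation). The falls numbered 2 without fresh P1 replicate 3 or MD replicate 1. Progenitor and Notch genes had 10 of 22 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.000149, adjusted p = 0.114 with an estimated correlation). Hes5 (-4.70, adjusted p = 1.95e-06) and Sox4 (-2.55, adjusted p = 7.17e-07) belonged to these. Cell cycle genes rose in 8 of 33 cases (8 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.7 with an estimated correlation).

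Other lists split. Matrix genes had 11 of 24 higher and 3 lower (11 and 3 adjusted over the list alone; camera adjusted p = 0.0602), mural genes 3 of 12 and 2 (3 and 2; 0.641), and fibroblast and meningeal genes 6 of 17 and 5 (6 and 5; 0.766), with 3 falls without fresh P1 replicate 2 or MD replicate 3. In all 1442 genes were higher and 1340 lower.

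Against HBEGF cultures of the same source age the MD cultures held more mitotic transcripts and more cytoskeletal targets of SRF. Mitotic genes such as Kif20a and Plk1 rose. Cxcl1 and Ccl7, chemokines that draw neutrophils and monocytes, and the small heat shock protein Hspb1 were strongly higher. Pdgfra and Bcas1, genes of oligodendrocyte progenitors, and the long noncoding RNA Miat were lower. Here the preparation and the medium differ together.

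Cxcl1 rose by 6.37 (adjusted p = 3.88e-07), the neuropeptide precursor Vgf by 5.97 (adjusted p = 4.34e-07), Mall by 5.79 (adjusted p = 1.08e-11), Gda by 5.78 (adjusted p = 1.14e-07), the muscle actin Acta1 by 5.73 (adjusted p = 1.09e-08), Ccl7 by 5.71 (adjusted p = 0.000162), Fstl3 by 5.69 (adjusted p = 1.71e-09) and Hspb1 by 5.68 (adjusted p = 6.95e-07). Miat (-6.12, adjusted p = 2.15e-07), Smoc1 (-5.78, adjusted p = 2.45e-07), Spon1 (-5.51, adjusted p = 2.87e-07), Slc22a3 (-5.49, adjusted p = 4.85e-07), Pdgfra (-5.49, adjusted p = 7.67e-06), Bcas1 (-4.92, adjusted p = 1.18e-06) and Gdpd2 (-4.79, adjusted p = 5.3e-07) fell, and so did Ptgds (-5.27, adjusted p = 0.0181; 0.0579 without HBEGF P1 replicate 3). Hbegf rose by 3.91 (adjusted p = 3.1e-05), whereas Egfr fell by 3.39 (adjusted p = 6.13e-08), Aldh1l1 by 2.35 (adjusted p = 1.29e-06) and Aqp4 by 1.41 (adjusted p = 0.000205). Gfap (-0.97, adjusted p = 0.0127), S100b (-0.89, adjusted p = 0.00179), Slc1a3 (-0.86, adjusted p = 0.00278) and Gja1 (-0.61, adjusted p = 0.000105) were lower but under the fold limit, and Slc1a2 (-0.08, adjusted p = 0.788) and Itgb5 (-0.24, adjusted p = 0.587) were not called.

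Of 33 cell cycle genes 30 rose (30 adjusted over the list alone; camera adjusted p = 1.14e-10, adjusted p = 0.288 with an estimated correlation). Kif20a (2.57, adjusted p = 8.68e-06), Ube2c (2.48, adjusted p = 9.37e-06) and Plk1 (2.38, adjusted p = 0.000148) were called. SRF targets rose in 15 of 19 cases (15 adjusted over the list alone; camera adjusted p = 9.2e-08, adjusted p = 0.0878 with an estimated correlation). Reactive astrocyte genes had 14 of 26 higher (15 adjusted over the list alone; camera adjusted p = 0.000126, adjusted p = 0.233 with an estimated correlation). In that list 1 member fell without MD replicate 2 or HBEGF P1 replicate 2 or 3. Matrix genes had 11 of 24 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.000391, adjusted p = 0.233 with an estimated correlation). Sterol synthesis had 8 of 20 lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 2.64e-06, adjusted p = 0.0878 with an estimated correlation), Lss (-1.96, adjusted p = 1.05e-06) and Insig1 (-1.92, adjusted p = 5.7e-06) leading. The fibroblast and meningeal list split: 5 of 17 rose and 7 fell (5 and 7 adjusted over the list alone; median -1.31, camera adjusted p = 0.616), the falls led by Lum (-4.70, adjusted p = 1.18e-06) and Dcn (-4.28, adjusted p = 0.000808). Igf2 fell too (-4.50, adjusted p = 0.0038), but another probe set for it moved in the opposite direction past adjusted p. All 3 called oligodendrocyte progenitor genes of 7 fell (3 adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.0878 with an estimated correlation), and so did 4 of 14 oligodendrocyte genes (4 adjusted over the list alone; camera adjusted p = 0.0926). For neuron genes 6 of 23 fell and 2 rose (6 and 2 adjusted over the list alone), with a median of 0.07, a mean of -0.55 and camera down at adjusted p = 0.392, so the list has no single direction. In all 1253 genes were higher and 1360 lower.

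**Figure D2:**
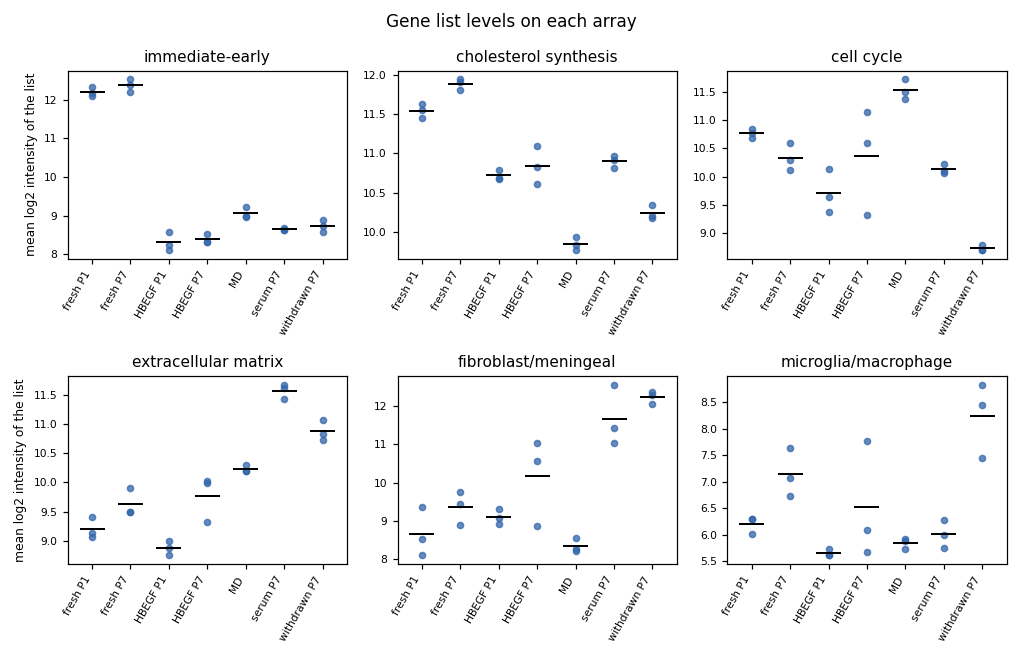
Mean log2 intensity of 6 gene lists on each array (points) in the 7 groups, with a bar at each group mean. The immediate-early list stands at 12.20 and 12.38 in fresh cells and at most at 9.06 in cultures, and the fibroblast and meningeal list at 11.67 and 12.24 in serum and withdrawn P7 cultures.

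Cultures of panned P7 cells held more matrix and contractile transcripts in serum than in HBEGF. Tnn, a tenascin, and the collagen genes Col1a1 and Col3a1 rose, as did Cnn1 and Acta2 of the contractile apparatus. Hspb1 and the acute-phase gene Serpina3n, which reactive astrocytes express, rose too. Egfr fell, and so did Spon1, the axon guidance protein F-spondin, and the neural transcription factor Sox3. Serum and the lack of HBEGF differ together here.

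Tnn went from 4.35 ± 0.11 (SD, n = 3) to 11.64 ± 1.00 (SD, n = 3), a change of 7.29 in log2 intensity (adjusted p = 7.51e-10) from a start that was not shown to exceed background. Next came Hspb1 (5.18, adjusted p = 8.99e-06), the keratin Krt19 (4.79, adjusted p = 8.75e-05), Thrsp (4.69, adjusted p = 2.44e-05), Thy1 (4.50, adjusted p = 3.96e-10), Ccn3 (4.37, adjusted p = 0.00131), Gda (4.33, adjusted p = 1.14e-05) and Inmt (4.03, adjusted p = 4.55e-05). Spon1 fell by 5.79 (adjusted p = 1.03e-06), Olfm3 by 4.38 (adjusted p = 3.91e-08) and Rlbp1 by 4.37 (adjusted p = 5.89e-07). Slc22a3 (-4.29, adjusted p = 2.98e-05), Itih3 (-3.98, adjusted p = 0.00084), Lhfpl3 (-3.98, adjusted p = 4.79e-05), Miat (-3.71, adjusted p = 0.000146) and Sox3 (-3.64, adjusted p = 2.86e-05) were lower as well. Egfr fell by 2.51 (adjusted p = 7.24e-06) and S100b by 1.16 (adjusted p = 0.000567; -0.94 without serum P7 replicate 3, under the fold limit). Gfap (0.40), Aqp4 (0.27), Aldh1l1 (0.43), Slc1a2 (0.32), Slc1a3 (-0.45), Gja1 (0.04), Itgb5 (-0.22) and Hbegf (0.47) were not called (adjusted p from 0.126 to 0.834).

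In the matrix list 18 of 24 rose (18 adjusted over the list alone; camera adjusted p = 9.16e-15, adjusted p = 0.021 with an estimated correlation). SRF targets rose in 11 of 19 cases (12 adjusted over the list alone; camera adjusted p = 2.47e-08, adjusted p = 0.0426 with an estimated correlation). Cnn1 (3.64, adjusted p = 0.000907), also in the mural list, and Actg2 (2.97, adjusted p = 3.27e-05) belonged to these. Mural genes had 4 of 12 higher (4 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.021 with an estimated correlation), Acta2 (1.94, adjusted p = 0.000389), Des (1.78, adjusted p = 0.000837) and Pdgfrb (1.37, adjusted p = 0.00369) after Cnn1. Fibroblast and meningeal genes rose in 9 of 17 cases (9 adjusted over the list alone; camera adjusted p = 4.85e-06, adjusted p = 0.407 with an estimated correlation), Serpinf1 (2.59, adjusted p = 0.000355), Col1a1 (2.47, adjusted p = 0.00038) and Col5a1 (2.18, adjusted p = 1.07e-05) first. With HBEGF P7 replicates 2 and 3 both left out, an alternative added after the data were seen, 5 fibroblast and 13 matrix genes rose. Reactive astrocyte genes had 10 of 26 higher and 1 lower (10 and 1 adjusted over the list alone; camera adjusted p = 4.45e-05, adjusted p = 0.327 with an estimated correlation). Serpina3n (3.51, adjusted p = 0.00198) and Fbln5 (3.20, adjusted p = 5.56e-06) were called. TGF-beta and BMP response genes rose in 6 of 17 cases (7 adjusted over the list alone; camera adjusted p = 1.73e-05, adjusted p = 0.0886 with an estimated correlation). Glycolysis had 2 of 18 higher (2 adjusted over the list alone; 1 without HBEGF P7 replicate 2; camera adjusted p = 0.0492, 0.0635 with a replicate block and adjusted p = 0.426 with an estimated correlation). Astrocyte genes showed no common direction: 1 of 28 rose and 3 fell (1 and 4 adjusted over the list alone), with a median of -0.09, a mean of -0.17 and camera up at adjusted p = 0.953. Their rises numbered 3 without HBEGF P7 replicate 1 or serum P7 replicate 3. In all 686 genes were higher and 636 lower.

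Serum P7 cultures held more astrocyte transcripts than MD cultures, with Aldh1l1, Aqp4 and Gfap higher, and far more Lum, Col3a1 and Dcn, matrix genes of fibroblasts. Mitotic genes and Hbegf were lower. Source age and preparation differ, and the astrocyte list stood at 12.32 and 11.5 in fresh P7 and P1 cells.

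Lum rose by 7.54 (adjusted p = 3.19e-08), Col3a1 by 7.33 (adjusted p = 9.9e-08), Colec12 by 7.13 (adjusted p = 5.1e-06), Tspan8 by 6.73 (adjusted p = 1.31e-05), Scara5 by 6.09 (adjusted p = 3.09e-05), Dcn by 6.04 (adjusted p = 6.58e-05), Thrsp by 5.97 (adjusted p = 1.24e-06) and Dab2 by 5.81 (adjusted p = 6.6e-07). Mall (-5.61, adjusted p = 2.31e-11), Cd93 (-5.24, adjusted p = 3.61e-08), Vgf (-5.19, adjusted p = 4.69e-06), Scg2 (-4.89, adjusted p = 1.5e-05), Slfn4 (-4.48, adjusted p = 3.04e-08), Npy (-4.35, adjusted p = 0.000326), Cxcl1 (-4.16, adjusted p = 6.3e-05) and Rasgrp3 (-4.13, adjusted p = 2.39e-07) fell. Aldh1l1 (2.79, adjusted p = 7.37e-07), Aqp4 (1.45, adjusted p = 0.000275) and Gfap (1.26, adjusted p = 0.00312; 0.92 without MD replicate 1, under the fold limit) rose, and Hbegf fell by 3.59 (adjusted p = 0.000137). Gja1 (0.69), Slc1a2 (0.64), Slc1a3 (0.49), S100b (0.03), Itgb5 (0.60) and Egfr (0.44) were not called (adjusted p from 6.23e-05 to 0.934, those under 0.05 below the fold limit).

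Of the fibroblast and meningeal list 12 of 17 rose (13 adjusted over the list alone; camera adjusted p = 2.27e-09, adjusted p = 0.217 with an estimated correlation). Astrocyte genes rose in 11 of 28 cases (11 adjusted over the list alone; camera adjusted p = 1.21e-07, adjusted p = 0.217 with an estimated correlation). Gpr37l1 (3.16, adjusted p = 4.5e-06) was called. Of these, 1 gene fell without serum P7 replicate 1. Cell cycle genes had 28 of 33 lower (29 adjusted over the list alone; camera adjusted p = 9.85e-10, adjusted p = 0.449 with an estimated correlation). Foxm1 (-1.92, adjusted p = 0.00114) and Mcm5 (-1.87, adjusted p = 0.000224) were among them. Sterol synthesis had 8 of 20 higher (8 adjusted over the list alone; camera adjusted p = 1.42e-09, adjusted p = 0.0598 with an estimated correlation). Tm7sf2 (2.66, adjusted p = 2.47e-07) and Insig1 (2.34, adjusted p = 1.96e-06) belonged to these. In all 1077 genes were higher and 906 lower.

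When serum was replaced by HBEGF medium for another week, mitotic transcripts fell and complement and macrophage transcripts came up. C3, the central complement component, had the largest rise, and Adgre1, Lyz2 and Fcer1g, all genes of macrophages, followed. The mitotic genes Ccna2, Bub1 and Mki67 fell. Tnn and Actg2, which were higher in serum than in HBEGF P7 cultures, fell. Egfr and Gfap were not called.

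C3 went from 6.67 ± 0.38 (SD, n = 3) to 13.88 ± 0.32 (SD, n = 3), a change of 7.21 (adjusted p = 6e-05). Adgre1 rose by 6.03 (adjusted p = 8.01e-05), the glycoprotein Chi3l1 by 5.61 (adjusted p = 6.18e-06), Lyz2 by 4.89 (adjusted p = 0.000309), Plac8 by 4.47 (adjusted p = 0.00597), Fcer1g by 4.45 (adjusted p = 0.000621), Steap4 by 4.41 (adjusted p = 0.00202) and the siderophore binder Lcn2 by 4.39 (adjusted p = 0.000662). Tnn (-4.03, adjusted p = 7.24e-06), Inmt (-3.60, adjusted p = 0.00057), Gpr155 (-3.31, adjusted p = 0.00137), Actg2 (-3.23, adjusted p = 8.01e-05), osteopontin, Spp1 (-3.19, adjusted p = 0.000917), Dusp2 (-2.95, adjusted p = 2.65e-05) and Mip (-2.77, adjusted p = 0.00278) fell, and so did Akr1b8 (-3.14, adjusted p = 0.0107; 0.0751 without serum P7 replicate 2). Slc1a2 fell by 1.24 (adjusted p = 0.0012) and S100b rose by 1.18 (adjusted p = 0.00183; 0.96 without serum P7 replicate 3, under the fold limit). Gfap (-0.08), Aqp4 (-0.09), Aldh1l1 (-0.19), Slc1a3 (-0.05), Gja1 (0.15), Itgb5 (-0.03), Hbegf (-0.45) and Egfr (0.37) were not called (adjusted p from 0.448 to 0.981).

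Of 33 cell cycle genes 23 fell (28 adjusted over the list alone; camera adjusted p = 4.41e-21, adjusted p = 0.21 with an estimated correlation). Ccna2 (-2.37, adjusted p = 0.00104), Bub1 (-2.26, adjusted p = 0.000432) and Mki67 (-2.13, adjusted p = 0.0019) were called. The count was 13 without serum P7 replicate 1, 11 without serum P7 replicate 2 and 12 without withdrawn P7 replicate 2. Microglia and macrophage genes rose in 12 of 18 cases (12 adjusted over the list alone; camera adjusted p = 9.04e-12, adjusted p = 0.21 with an estimated correlation), the complement genes C1qb (4.18, adjusted p = 0.00512) and C1qa (4.15, adjusted p = 0.0026) after Lyz2 and Fcer1g. Sterol synthesis was lower by camera at a median of -0.68 (adjusted p = 3.03e-10, adjusted p = 0.0494 with an estimated correlation), although only Cyp51 of 20 was called (-1.09, adjusted p = 0.000805; -0.93 without withdrawn P7 replicate 2; 1 adjusted over the list alone). The count was 4 without withdrawn P7 replicate 3 and 2 without serum P7 replicate 1 or 3 or withdrawn P7 replicate 1. Matrix genes fell in 3 of 24 cases (4 adjusted over the list alone; 1 without serum P7 replicate 2; camera adjusted p = 4.68e-05, adjusted p = 0.21 with an estimated correlation). Col8a1 (-2.26, adjusted p = 0.00502) and Tnc (-2.71, adjusted p = 0.0126; 0.0719 without serum P7 replicate 1) were among them. SRF targets had a median of -0.50 and 1 of 19 lower, Actg2 (1 adjusted over the list alone; 3 without serum or withdrawn P7 replicate 3; camera adjusted p = 0.00024, adjusted p = 0.21 with an estimated correlation). Of the secreted factors that act on synapses 2 of 15 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.311), the rises being Thbs4 (3.43, adjusted p = 0.000916) and Apoe (1.41, adjusted p = 1.11e-05). The falls numbered 0 without serum P7 replicate 1 or 2 or withdrawn P7 replicate 1. In all 319 genes were higher and 321 lower, 640 together, but 337 without serum P7 replicate 2, 413 without serum P7 replicate 1 and 954 without serum P7 replicate 3.

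A week after serum, the withdrawn cultures still differed from cultures that never saw it. Lcn2, a marker of reactive astrocytes, C3 and Hspb1 were higher, and the matricellular gene Ccn3 with them. Spon1, Sox3 and Egfr remained lower. Olig1, a transcription factor of the oligodendrocyte lineage, and the mitotic gene Mki67 were lower too. Time in culture differs between these groups as well, 14 days against 7.

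Lcn2 rose by 6.28 (adjusted p = 8.32e-06), E-cadherin, Cdh1, by 5.19 (adjusted p = 2.88e-06), Ccn3 by 5.16 (adjusted p = 0.00038), Krt19 by 5.16 (adjusted p = 5.6e-05), C3 by 5.14 (adjusted p = 0.000246), Slc13a4 by 5.14 (adjusted p = 0.00246), Hspb1 by 4.80 (adjusted p = 2.58e-05) and Lyz2 by 4.71 (adjusted p = 9.42e-05). Spon1 (-5.25, adjusted p = 4.54e-06), Olfm3 (-4.88, adjusted p = 2.57e-08), Sox3 (-4.37, adjusted p = 7.6e-06), Rlbp1 (-4.23, adjusted p = 9.74e-07), Slc22a3 (-4.23, adjusted p = 4.31e-05), Bcas1 (-4.09, adjusted p = 4.78e-05), Olig1 (-4.08, adjusted p = 0.00196) and Plppr4 (-3.94, adjusted p = 0.000269) fell. Egfr fell by 2.15 (adjusted p = 4.12e-05), and Slc1a2 (-0.93, adjusted p = 0.00278) stayed under the fold limit. Gfap (0.32), Aqp4 (0.18), Aldh1l1 (0.24), Slc1a3 (-0.50), Gja1 (0.19), S100b (0.02), Itgb5 (-0.26) and Hbegf (0.02) were not called (adjusted p from 0.0793 to 0.983).

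Of 33 cell cycle genes 30 fell (31 adjusted over the list alone; camera adjusted p = 1.69e-15, adjusted p = 0.162 with an estimated correlation), Mki67 (-2.65, adjusted p = 9.8e-05) and Bub1b (-2.21, adjusted p = 0.000169) first. With HBEGF P7 replicates 2 and 3 both left out, added after the data were seen, only 4 fell, and 6 fibroblast, 5 interferon and 2 endothelial genes of the lists below rose. Reactive astrocyte genes rose in 13 of 26 cases and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 5.69e-07, adjusted p = 0.144 with an estimated correlation). Fibroblast and meningeal genes rose in 13 of 17 cases (14 adjusted over the list alone; camera adjusted p = 4.42e-07, adjusted p = 0.162 with an estimated correlation). The retinoic acid enzyme Aldh1a2 (3.51, adjusted p = 0.00441) and Crabp2 (3.11, adjusted p = 0.00192) were called. The count was 8 without HBEGF P7 replicate 2 or withdrawn P7 replicate 3. Microglia and macrophage genes rose in 9 of 18 cases (12 adjusted over the list alone; 4 without HBEGF P7 replicate 2; camera adjusted p = 2.25e-06, adjusted p = 0.189 with an estimated correlation). Interferon and antigen presentation genes rose in 13 of 19 cases (16 adjusted over the list alone; camera adjusted p = 5.69e-07, adjusted p = 0.162 with an estimated correlation), Gbp2 (2.14, adjusted p = 0.00538) and Irf7 (2.10, adjusted p = 0.000942) among them, but in 5 without HBEGF P7 replicate 2, 6 without withdrawn P7 replicate 1 and 8 without withdrawn P7 replicate 2. Endothelial genes had 5 of 14 higher (5 adjusted over the list alone; camera adjusted p = 0.000618, adjusted p = 0.162 with an estimated correlation). The drug exporter Abcb1a (3.76, adjusted p = 0.00057) was among them. In all 894 genes were higher and 770 lower.

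**Figure D3:**
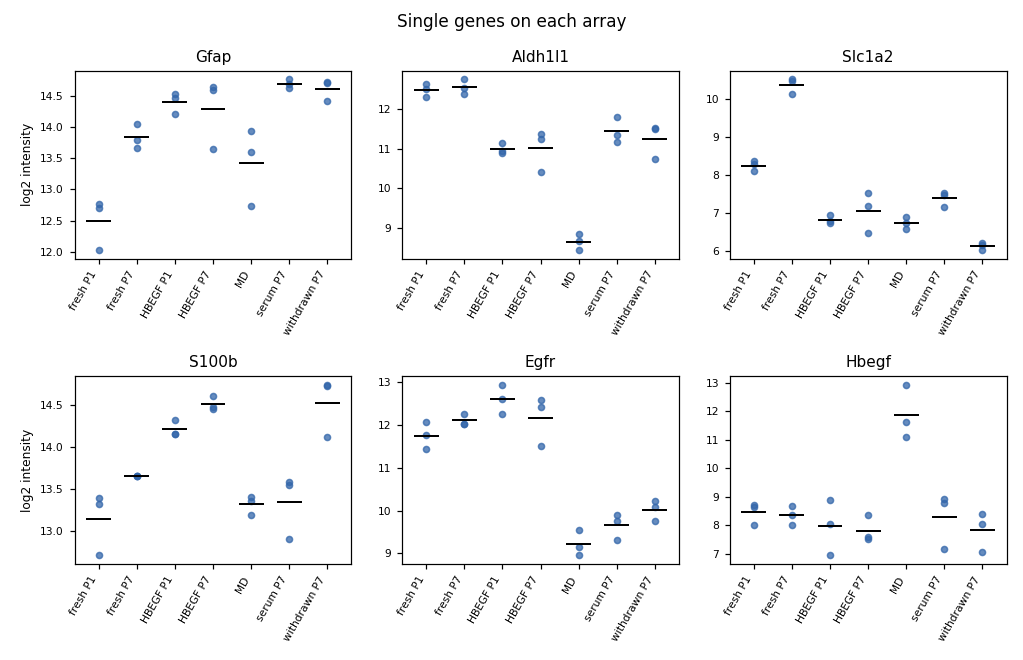
Log2 intensity of 6 core genes on each array (points) in the 7 groups, with a bar at each group mean. Egfr stands at 12.60 and 12.17 in HBEGF cultures and at 9.66 and 10.02 in serum and withdrawn cultures.

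The difference between serum and HBEGF P7 cultures overlapped with the MD difference. Egfr, Spon1 and Slc22a3 fell and Gda and Hspb1 rose in both, and these comparisons share no arrays. Both held 730 genes of the same sign, 332 higher and 398 lower, where independent lists would give 60.5 and 60.8; 31 had opposite signs, and r over all genes was 0.53 (covariance 0.346).

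Reversal after serum removal was partial, and time in culture differs too. Of 1322 genes called in serum against HBEGF P7 cultures, 764 were still called with the same sign in withdrawn against HBEGF P7 cultures, like Spon1, Egfr and Krt19. A further set of 188 was called back against serum, like Tnn and Inmt, 27 of them in both sets, 397 were in neither, and 19 had moved further. Of the 686 higher genes 404 were still called and 113 called back, and of the 636 lower genes 360 and 75. Independent lists would share 43.1 and 34.4 genes, 8 genes had opposite signs, and r was 0.71 with a covariance of 0.374. These comparisons share the HBEGF P7 arrays, and 100 simulations with unchanged groups gave a mean r of 0.50 and a covariance of 0.033. The simulations gave every group the same variance, although the HBEGF P7 arrays spread more. The 3 control arrays cannot be split, so a part of the overlap may come from them.

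A further measure used genes called between MD and HBEGF P1 cultures, whose log2 changes use no P7 array. The variance behind these calls came from all 21 arrays, P7 arrays included. The medians are still taken against the same 3 HBEGF P7 arrays. Of the 1253 genes higher in MD than in HBEGF P1 cultures, the median change was 0.49 in serum and 0.18 in withdrawn against HBEGF P7 cultures, a ratio of 0.37, with 74.1% and 58.3% in the same direction. For the 1360 lower genes the medians were -0.66 and -0.41, a ratio of 0.62, with 84.9% and 74.0% in the same direction. Array medians of the higher genes were 0.45 ± 0.12 (SD, n = 3) in serum and 0.18 ± 0.03 (SD, n = 3) in withdrawn cultures. The exact two-sided permutation p was 0.1 for each pair of groups, the lowest possible.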

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

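The tests of explanations in this part were chosen only after the results were seen; the test of the difference between ages was chosen before.

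The test of whether culture in HBEGF acts differently on P7 than on P1 cells called 116 genes. The differences of Penk (3.54), S100a6 (3.30), Esm1 (3.23), Cldn5 (2.52) and Tpm2 (2.43) were the largest positive ones, and those of Pcdh20 (-4.05), Gabbr2 (-3.95), Hspa1a (-3.70), Omg (-3.02) and Agt (-2.99) the largest negative ones. Source age is the difference that the design names, and it was not separated from preparation day or other differences between litters.

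Fibroblast and meningeal markers were higher in serum and withdrawn P7 cultures than in HBEGF P7 cultures, with Col3a1 at 14.36 and 14.15 against 12.20 and Col1a2 at 14.38 and 14.02 against 12.56. The list shares 0 genes with the other lists, and 16 of its 17 members exceeded the median of all values (7.11) in fresh P1 or P7 cells. Fibroblasts among the P7 cells are a candidate explanation: within groups, over 9 arrays, its members moved together (mean correlation 0.57 against 0.01 for the median of 1000 random lists, percentile 100), although regulation in common could give the same. Induction by serum, or by the lack of HBEGF, stays open too: in MD against HBEGF P1 cultures, which also differ in preparation, the median was -1.31, but 5 of 17 members rose and 7 fell, so it decides nothing.

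Microglia and macrophage markers were higher after serum removal, with Lyz2 at 13.06 against 8.17 and C1qc at 10.50 against 6.88. Of 18 members 10 exceeded that median in fresh P1 or P7 cells. The members moved together within groups (mean correlation 0.57, percentile 100), which macrophages among the cells would give and regulation in common could also give. A lower share of astrocytes that raised other types alike is argued against, as the fibroblast median change was 0.19 against 2.48. Panning on ITGB5 was the only sort named. Macrophage growth, even replacing astrocytes, or induction in other cells stays open.

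Immediate-early genes were lower in every culture than in fresh cells. The serum-free medium alone cannot be the reason, since MD cultures in serum had a median of -3.36. A response to dissociation and panning and a true fall in culture cannot be told apart, because every fresh group was dissociated: the median between the fresh groups was 0.17, which both would allow.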

How the results depend on the processing

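The alternatives in this part were chosen before the data were examined, except the one without HBEGF P7 replicates 2 and 3, chosen after the data were seen.

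Of 105 list results under 1320 alternatives, 1139 were the same and 181 weaker, and 93 lists lost their call under at least 1 alternative, with 12 kept by the estimated correlation. Of 811 gene results under 8921 alternatives, 8093 were the same, 735 weaker, 32 stronger and 61 reversed, and 239 lost their call under at least 1. With 3 arrays per group, leaving out 1 leaves 2, and the lone HBEGF P7 array without replicates 2 and 3 is assumed to vary like the other groups. Centring arrays on their medians shifted MD against HBEGF P1 cultures by a median of 0.11. A replicate block ended the calls of Fbln5 in HBEGF P7 against P1 cultures (adjusted p = 0.0531) and Gap43 in withdrawn against serum P7 cultures (0.0556). It added Hes5 (0.0407) and Fcer1g (0.0328) in HBEGF P7 against HBEGF P1 cultures and Etv5 (0.0321) in withdrawn against serum P7 cultures, and beside the blocked values in the report it changed no other list or gene call described there.

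Counts of genes moved by more than 1.5 times in these cases. Causes were not tested. Array weights gave 336 for fresh P7 against P1 cells, 1168 for withdrawn against serum and 185 for the difference of differences. Dropping the fold limit, which can only add genes, gave 619 for fresh P7 against P1 cells, 3418 and 4060 for HBEGF P1 and P7 cultures against fresh cells, 249 for HBEGF P7 against P1, 6154 for MD against fresh P1, 6007 for MD against HBEGF P1, 3592 for serum against HBEGF P7, 1417 for withdrawn against serum, 4244 for withdrawn against HBEGF P7 and 4846 for serum against MD. A stricter p gave 117 for fresh P7 against P1 cells, 50 for HBEGF P7 against P1, 347 for withdrawn against serum and 39 for the difference of differences. Testing against a fold of 1.5, a harder test, gave 29, 610, 762 and 8 for the first 4 comparisons in this order, 523 for serum against HBEGF P7, 86 for withdrawn against serum, 662 for withdrawn against HBEGF P7, 1143 for serum against MD and 17 for the difference of differences. Fits on the compared groups only, which have fewer degrees of freedom, gave 0 in limma for HBEGF P7 against P1 (357 at unadjusted p under 0.05 past the fold limit), 762 for serum against HBEGF P7, 895 for withdrawn against HBEGF P7 and 58 for the difference of differences. Without HBEGF P7 replicates 2 and 3 there were 1091 for withdrawn against HBEGF P7 and 62 for the difference of differences. Leaving out 1 array gave 136 to 213 for fresh P7 against P1 cells, 75 to 291 for HBEGF P7 against P1, 337 to 954 for withdrawn against serum and 50 to 343 for the difference of differences. The ratio for genes higher in MD cultures (0.37) was 0.28 with an intensity filter, 0.31 with a stricter p, and 0.28 to 0.42 with 1 array left out.

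All reversed values belong to core genes that were not called. With the mean of all probe sets of a gene these were Itgb5 in fresh P7 against P1 cells (-0.04), Egfr in HBEGF P7 against fresh P7 (-0.26), Slc1a3 (-0.10) and Gja1 (-0.19) in HBEGF P7 against P1, Aqp4 (-0.04) and Slc1a3 (0.04) in serum against HBEGF P7, Aqp4 (0.01) and Egfr (-0.06) in withdrawn against serum, and Aqp4 in withdrawn against HBEGF P7 (-0.03). Centring gave Slc1a2 0.03 in MD against HBEGF P1 and S100b -0.04 in serum against MD, and repeated quantile normalization gave S100b -0.03 in withdrawn against HBEGF P7. With 1 array left out, the values crossed 0 for Aldh1l1 (-0.04 to 0.15), Itgb5 (-0.05 to 0.18) and Hbegf (-0.33 to 0.07) in fresh P7 against P1 cells, and for Hbegf (-0.96 to 0.02) in HBEGF P1 against fresh P1. In HBEGF P7 against fresh P7 they did so for Gja1 (-0.08 to 0.01) and Egfr (-0.15 to 0.39), and in HBEGF P7 against P1 for Gfap (-0.28 to 0.22), Aqp4 (-0.47 to 0.18), Aldh1l1 (-0.17 to 0.31), Slc1a3 (-0.03 to 0.14), Gja1 (0 to 0.10) and Hbegf (-0.65 to 0.32). In MD against fresh P1 it was S100b (-0.04 to 0.30), and in MD against HBEGF P1 Slc1a2 (-0.16 to 0). Aqp4 (-0.13 to 0.51), Gja1 (-0.06 to 0.11) and Itgb5 (-0.43 to 0.19) crossed in serum against HBEGF P7. Gfap (-0.13 to 0.02), Aqp4 (-0.18 to 0.05), Aldh1l1 (-0.33 to 0.07), Slc1a3 (-0.28 to 0.22) and Itgb5 (-0.44 to 0.37) did in withdrawn against serum. In withdrawn against HBEGF P7 these were Gfap (0 to 0.49), Aqp4 (-0.22 to 0.42), Aldh1l1 (-0.06 to 0.50), S100b (-0.09 to 0.22), Itgb5 (-0.47 to 0.15) and Hbegf (-0.26 to 0.41), and in serum against MD S100b (-0.09 to 0.25). The cause was not tested.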

Other observations

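The splits in this part were chosen before the results were seen; those with the mean age difference subtracted, and leaving out HBEGF P7 replicates 2 and 3 together, only after.

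Interferon and antigen presentation genes were higher in serum P7 than in MD cultures, 9 of 19 called (9 adjusted over the list alone; 5 without serum P7 replicate 1; median 1.15, camera adjusted p = 0.000268, adjusted p = 0.449 with an estimated correlation). TGF-beta and BMP response genes rose in 5 of 17 cases in withdrawn against HBEGF P7 cultures (6 adjusted over the list alone; 2 without HBEGF P7 replicate 2, 1 without withdrawn P7 replicate 3 or without HBEGF P7 replicates 2 and 3 together; camera adjusted p = 0.000292, adjusted p = 0.144 with an estimated correlation). The HBEGF P7 arrays had the lowest median rank correlation within a group, 0.974. On replicates 1, 2 and 3 their microglia list stood at 6.09, 5.68 and 7.77 and their cell cycle list at 9.33, 11.14 and 10.6. Against fresh P7 cells (10.33) the sign varied: 2 of 33 cell cycle genes rose and 0 fell, or 0 and 2 without HBEGF P7 replicate 2.

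Each comparison of 3 against 3 arrays has 10 splits of its 6 arrays, so the share of splits that call as many genes cannot go under 0.05, and it was 1 of 10 in each. Real and highest other counts were 221 and 0 for fresh P7 against P1 cells, 1261 and 1 for HBEGF P1 and 1463 and 17 for HBEGF P7 cultures against fresh cells, and 158 and 77 for HBEGF P7 against P1. They were 2782 and 0 for MD against fresh P1, 2613 and 0 for MD against HBEGF P1, 1322 and 79 for serum against HBEGF P7, 640 and 135 for withdrawn against serum, 1664 and 49 for withdrawn against HBEGF P7 and 1983 and 1 for serum against MD. Where numbers paired, 3 other splits part every pair. They called at most 1 gene for withdrawn against serum and 0 in the other 4 paired comparisons, while the splits with 77 and 135 keep pairs together.

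For the difference of differences (116 genes, 167 with a replicate block), ages were exchanged within fresh and within cultured arrays, without regard to pairs, and 6 of 100 splits called as many. The highest other, 462, exchanged all culture ages, and it and the other 4 with more than 116 kept the true fresh ages, so they carry the age structure of the samples and decide nothing about chance. With each gene's mean age difference subtracted beforehand, 1 of 100 splits, the real one, called as many, and the highest other called 71. That difference was estimated with the true ages and cancels in the true contrast, so the real count was fixed at 116. Only the other splits could change, so this later test does not decide about chance either.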
